A study of Mus musculus with 3 samples.

How the data were processed

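RNA was measured by sequencing in 3 libraries of BALB/c mouse splenic T lymphocytes cultured with LZ-8 for 15 h. Per the labels' protocols, T cells were isolated with a bead kit against CD90.2, kept in medium with fetal bovine serum, and their RNA was extracted with Trizol and made into libraries with an Ion Proton RNA-seq kit. The authors deposited 1 table of raw read counts per gene symbol, with 1 column for each library. The values are whole numbers with a different total in each column, 12669690 to 19041670, so they were taken as unnormalized counts. The build mm10 is named in the submitters' processing notes. The aligner, the counting tool, the annotation and the treatment of reads that map to several places are not given in the sources used here, nor is the use of strand. Genes that share sequence, overlap or lie antisense to each other may therefore have gained or lost reads. No column of another sample was present.

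The 3 libraries were 1 group in the labels. No contrast between groups could be fitted, so edgeR's quasi-likelihood test, the usual choice for counts, was not applicable. CPM is counts divided by the library total and multiplied by 1000000, and a level is given as the mean CPM with the SD over the libraries. Effective library sizes for comparisons between libraries used edgeR's TMM factors, which lay within 0.996 and 1.003. Genes with a CPM of at least 1 in at least 2 libraries were tested for differences between the libraries with edgeR 4.0.16 (glmFit with dispersion 0, likelihood-ratio test, Benjamini-Hochberg adjustment), and the biological coefficient of variation came from estimateDisp with only an intercept. On Poisson counts simulated from the means of the 13500 tested genes, this test recovered 79 of 100 genes changed 1.5-fold and 85 of 100 changed 2-fold in 1 library, with 12 false calls. The coefficient was 0.0394 in that simulation and 0.00988 without changed genes, so a small set of genes can raise it.

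The gene lists, gene pairs, tests, rule for named genes and other settings were fixed before the data were examined. There were 30 lists with 338 entries (326 distinct genes), 20 for T cell states and pathways and 10 for markers of other cell types, and 337 entries were in the table, 4 of them under an older symbol. Eligible to be named, though not all are, were at most 4 members of each list with the highest mean CPM, every gene of 12 fixed ratios, the 20 most abundant genes outside the mitochondrial and ribosomal protein genes, and the 10 widest-ranging genes of at least 10 CPM among those that varied. The table names mitochondrial genes without a prefix, so they were recognised by their RefSeq chromosome. A list's level was the median of log2(mean CPM + 1), set against 10000 random lists of the same size. Pairs of lists were compared by permuting membership over genes (100000 resamples, or exact for Th1 against Th2). Ratios of read counts within a library had 0.5 added to each count, exact (Clopper-Pearson) 95% intervals per library and an exact sign-flip test over the libraries. The spread of a list's summed level between libraries was set against random lists matched on expression in 20 bins. Checked on simulated data, the list tests recovered shifted lists and did not call the unshifted ones, and the pair test called all shifted pairs and slightly more than its nominal share of unshifted pairs.

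Exon lengths, positions and shared sequence came from GENCODE vM21 (GRCm38, the assembly that mm10 denotes). Of the 44788 symbols 33837 matched a RefSeq name or synonym and 32248 had an exon length, as did 99.4% of the list entries. Sharing is the percentage of a gene's 31-mers also found in transcripts of another gene, overlapping genes included. Alternatives covered DESeq2 1.42.0 size factors, unscaled totals, other expression filters, length-scaled values, other pseudocounts, means in place of medians and each library left out. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.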

Results

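RNA-seq gene counts were available from 3 libraries of mouse splenic T lymphocytes that had been cultured with LZ-8 for 15 h. LZ-8 (Ling Zhi-8) is a small immunomodulatory protein of the medicinal fungus Ganoderma lucidum that acts on T cells as a mitogen. The T cells came from BALB/c mice and were taken from the splenocyte suspension with magnetic beads against CD90.2 (Thy1), a surface protein of mouse T cells. The 3 libraries form a single group, so the comparisons below lie within the libraries (between genes and between gene groups) and between the replicates; untreated cells were not analysed here, and no value below is a response to LZ-8. The labels do not say whether the replicates came from separate mice or cultures, so the spread between them may be technical. The libraries held 19041670, 12669690 and 14715992 counts (replicates 1, 2 and 3). Of the 44788 gene symbols listed, 20896, 19814 and 20117 had at least 1 read, and 13531 ± 17.4 (SD, n = 3) reached 1 CPM (counts per 1000000 counts). A count of 0 allows a level of up to 0.158, 0.237 and 0.204 CPM in the respective libraries. Intervals and such limits cover counting error only.

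The first question was which transcripts dominated the treated T cells. The gene with the highest level outside the mitochondrial and ribosomal protein genes was Rn18s-rs5, annotated as a pseudogene of ribosomal RNA, at 9820 ± 1037 CPM (SD, n = 3). It was followed by translation and folding genes: Eef1a1 (translation elongation factor) at 7958 ± 280 CPM, Hsp90ab1 (a heat shock protein chaperone) at 6477 ± 144 CPM and Eef2 (translation elongation factor) at 4783 ± 139 CPM. Irf4, a transcription factor induced by T cell receptor signalling, was the only transcription factor among the 20 most abundant genes, at 2410 ± 101 CPM. Irf4 lies on chromosome 13 at 30749226 to 30766976 (GRCm38). The same group held Srrm2 (2139 ± 37.4 CPM), the class I MHC gene H2-D1 (2100 ± 40.5 CPM), Actb (2055 ± 50.7 CPM), Myh9 (1879 ± 40.9 CPM), Ncl (nucleolin; 1784 ± 22.5 CPM), Pabpc1 (1706 ± 13.8 CPM), Ptprc (CD45; 1705 ± 11.1 CPM), Gnb2l1 (1690 ± 59.8 CPM), Ldha (lactate dehydrogenase; 1640 ± 65.9 CPM), Lars2 (2414 ± 404 CPM) and the nuclear long non-coding RNA Malat1 (1582 ± 210 CPM). Another 3 of the 20 were annotated pseudogenes, Gm13456, Gm8730 and Gm15459, at 4508 ± 420 CPM, 2045 ± 56.0 CPM and 1715 ± 26.4 CPM. Of their 31-mers, 73.2%, 88.3% and 96.9% also occurred in transcripts of another gene, so these levels, like that of Eef1a1 with 49.8% shared, are uncertain. Rn18s-rs5 had no sharing value, and whether its reads came from ribosomal RNA itself was not tested. Lars2 stood at 2846, 2350 and 2046 CPM in replicates 1, 2 and 3, falling in the same order as Rn18s-rs5 (10918, 9686 and 8858 CPM) and Malat1 (1781, 1600 and 1364 CPM). The origin of the Lars2 reads was not tested either, and the sharing value covers annotated transcripts only. Mitochondrial genes took 2.43 ± 0.130% of counts and protein-coding ribosomal protein genes 2.60 ± 0.0671%, while annotated pseudogenes took 10.8 ± 0.127% (SD, n = 3). The pseudogene share includes Rn18s-rs5 (0.982 ± 0.104%) and pseudogene copies of ribosomal protein genes. Reads of those copies may stem from the coding genes, so the ribosomal protein share may be too low.

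The libraries had the transcripts of T cells and almost none of other leukocytes, erythroid cells or platelets. All 16 T cell identity genes were present, 14 of them above 100 CPM. Their summed level was 6253 ± 89.2 CPM (SD, n = 3), with Cd6 (993 ± 17.2 CPM), Cd5 (658 ± 21.3 CPM) and the T cell receptor kinase Lck (522 ± 11.6 CPM) among the highest. The 12 B cell markers summed to 23.3 ± 2.18 CPM, with Pax5 at 3.84 ± 0.941 CPM, Ms4a1 at 3.06 ± 0.557 CPM and Blnk at 1.94 ± 0.151 CPM. The 12 monocyte and macrophage markers summed to 4.88 ± 0.621 CPM, most of it Cd68 (4.08 ± 0.406 CPM). Csf1r, C1qa, C1qc and Fcgr1, singled out after their values were seen, had no read in any library. The 11 neutrophil genes summed to 0.358 ± 0.281 CPM and the 11 erythroid genes listed to 2.53 ± 0.0899 CPM, with the globin gene Hba-a2 at 0.955 ± 0.145 CPM. Natural killer cell genes summed to 30.7 ± 1.55 CPM, mainly Eomes (17.5 ± 1.59 CPM) and Klrk1 (10.7 ± 0.154 CPM), which activated CD8 T cells also express. Single members stood apart in the remaining lists, namely Xbp1 (129 ± 4.25 CPM) and Prdm1 (16.7 ± 1.21 CPM) among the plasma cell genes, Zbtb46 (9.49 ± 1.22 CPM) among the dendritic cell genes, Itga2b (8.25 ± 0.292 CPM) among the platelet genes, Kit (8.24 ± 1.23 CPM) among the mast cell and basophil genes and Pecam1 (61.8 ± 2.18 CPM) among the stromal and endothelial genes. In all, 28 of the 91 other-cell markers had no read in any library, against 0 of the 246 entries of the T cell state and pathway lists. The 28 include Hbb-b1 and Hbb-b2, which had no position or exon length in GENCODE, so their lack of reads may not reflect the cells. Whether BALB/c mice carry every listed gene was not checked.

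The median T cell identity gene lay 6.68 log2 units above the median B cell gene and 8.03 above the median monocyte and macrophage gene. Both differences passed a two-sided permutation test of list membership (100000 resamples, adjusted p = 0.0011 and 0.0049 over 5 pairs of lists). They were of similar size in each library, with an SD over the replicates of 0.13 and 0.03 log2 units. Cd3e had 7484, 5433 and 6299 reads, against 36, 22 and 25 for the B cell receptor gene Cd79a and 5, 0 and 2 for the macrophage and granulocyte gene Lyz2.

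**Figure D1:**
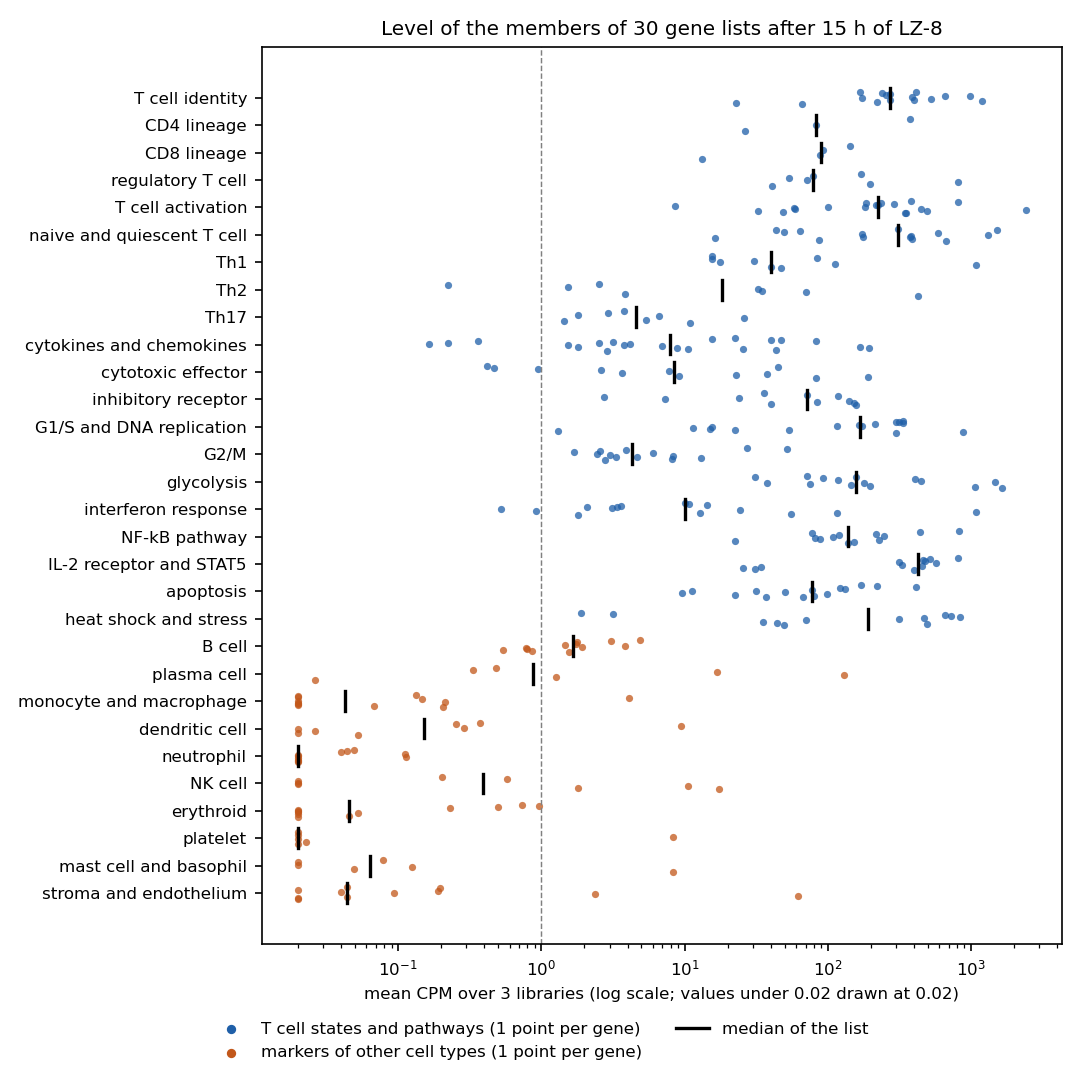
Mean CPM over the 3 libraries (x axis, log scale) of every listed member of 30 gene lists (rows), with the median of each list as a black bar and a dashed line at 1 CPM. The T cell and pathway lists (blue) have medians from 4.29 CPM (G2/M) to 429 CPM (IL-2 receptor and STAT5), whereas the highest median among the markers of other cell types (orange) is 1.66 CPM (B cell).

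The series title names CD4 and CD8 T cells, so the balance between lineage transcripts was measured. Cd4 reads outnumbered Cd8a reads 2.63-fold and Cd8b1 reads 4.08-fold, in each of the 3 libraries. Cd4 (chromosome 6, 124864692 to 124888221) stood at 376 ± 11.2 CPM, and Cd8a (chromosome 6, 71373427 to 71379173) at 143 ± 2.65 CPM (SD, n = 3). Cd4 made up 71.6% of the reads of Cd4 and Cd8a in replicate 1 (exact 95% interval 70.7 to 72.5%), 73.0% in replicate 2 (71.9 to 74.0%) and 72.8% in replicate 3 (71.8 to 73.8%). The mean log2 ratio was 1.40 ± 0.05 for Cd4 to Cd8a and 2.03 ± 0.02 for Cd4 to Cd8b1. The lineage regulator Zbtb7b (ThPOK, of CD4 cells) was at 82.5 ± 3.51 CPM and Runx3 (of CD8 cells) at 87.9 ± 4.37 CPM. Cd40lg, the CD40 ligand, was at 26.5 ± 1.71 CPM and Crtam at 13.2 ± 1.80 CPM. Foxp3, the defining transcription factor of regulatory T cells, was at 170 ± 8.17 CPM, with a Foxp3 to Cd4 log2 ratio of -1.15 ± 0.04, and other regulatory T cell genes were Tnfrsf18 (197 ± 7.21 CPM) and Ikzf2 (79.3 ± 8.15 CPM). An exact sign-flip permutation test of each of the 12 ratios over the libraries gave p = 0.25, raw and adjusted, the smallest that 3 libraries allow, so none could pass a threshold of 0.05. A count ratio between genes also depends on transcript length. Per kilobase of exon the log2 ratio was 1.25 for Cd4 to Cd8a and 0.58 for Cd4 to Cd8b1.

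Transcripts of T cell activation and of the resting state were both abundant. All 19 activation genes were above 1 CPM and 13 above 100 CPM, including Irf4, the IL-2 receptor alpha chain Il2ra (816 ± 19.2 CPM, chromosome 2, 11642807 to 11693193), the transferrin receptor Tfrc (494 ± 15.4 CPM) and Myc (451 ± 14.9 CPM). All 15 genes of the naive and quiescent list were above 1 CPM and 10 above 100 CPM, with the lymph node homing receptor Ccr7 at 1523 ± 34.5 CPM, Satb1 at 1311 ± 17.9 CPM, Slfn2 at 665 ± 5.40 CPM and Tcf7 at 592 ± 10.9 CPM. The medians of the 2 lists differed by -0.48 log2 units (activation minus naive), and per kilobase of exon the sign turned to 0.84. Neither passed the permutation test, with adjusted p = 0.589 and 0.547.

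Genes of the IL-2 receptor pathway formed the list with the highest median, 429 CPM. Of its 12 members 9 were above 100 CPM, among them Il2ra, the signal transducer Stat5a (569 ± 18.1 CPM), the receptor beta chain Il2rb (515 ± 25.5 CPM) and the kinase Jak1 (479 ± 17.8 CPM). The NF-kB list had all 13 members above 1 CPM and 9 above 100 CPM, led by Nfkb1 (827 ± 13.5 CPM), Nfkb2 (440 ± 15.1 CPM) and the inhibitors Nfkbia (246 ± 9.63 CPM) and Tnfaip3 (226 ± 7.91 CPM). All 15 glycolysis genes were above 1 CPM, led by Ldha, Aldoa (1467 ± 36.6 CPM), Pkm (1076 ± 49.8 CPM) and Pfkp (448 ± 14.6 CPM). In the chaperone and stress list Hspa8 (834 ± 26.6 CPM), Hspa5 (726 ± 20.9 CPM), Hsp90aa1 (656 ± 13.6 CPM) and Atf4 (495 ± 3.05 CPM) were highest. In the apoptosis list the survival genes Mcl1 (417 ± 13.6 CPM), Bcl2l1 (223 ± 4.25 CPM) and Bcl2 (170 ± 3.68 CPM) and the effector Bax (132 ± 5.07 CPM) had the highest counts. Per kilobase of exon Bax (83.5 ± 3.22 CPM) was above Bcl2l1 (48.5 ± 0.927 CPM) and Bcl2 (18.6 ± 0.402 CPM) and below Mcl1 (122 ± 3.97 CPM). The Bcl2 to Bax log2 ratio was 0.37 ± 0.03, and it reversed to -2.17 per kilobase of exon.

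The cytokine and chemokine list had a median of 7.94 CPM, and Il2 was far below the IL-2 receptor gene Il2ra. The highest members of the cytokine and chemokine list were Tnfsf8 (CD30 ligand; 194 ± 9.07 CPM), Tgfb1 (168 ± 4.36 CPM), Ltb (83.2 ± 7.81 CPM) and Lta (46.8 ± 2.03 CPM), and 3 of the 22 genes were under 1 CPM. Il2 stood at 22.4 ± 2.26 CPM, Ifng at 15.6 ± 1.05 CPM, Il17a at 3.79 ± 0.304 CPM and Il4 at 2.55 ± 0.516 CPM (SD, n = 3). Ifng reads outnumbered Il4 reads 6.12-fold (log2 ratio 2.61 ± 0.38) and Il17a reads 4.08-fold (2.03 ± 0.03), and Il2 reads outnumbered Ifng reads 1.44-fold (0.52 ± 0.09), each in 3 of 3 libraries. Members of the Th1 list included Stat4 (113 ± 1.25 CPM) and the Th1 master regulator Tbx21 (84.8 ± 3.03 CPM). The highest of the Th2 list were Stat6 (427 ± 6.33 CPM), Ccr4 (70.1 ± 2.25 CPM), Maf (34.5 ± 2.31 CPM) and the Th2 master regulator Gata3 (32.7 ± 0.627 CPM), and the Th17 list included Rora (25.8 ± 0.957 CPM), Ahr (11 ± 0.786 CPM) and Ccr6 (5.34 ± 0.905 CPM). The Th1 median exceeded the Th2 median by 1.69 log2 units, which did not pass the exact permutation test (adjusted p = 0.083) but did per kilobase of exon (2.90, adjusted p = 0.0111).

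Genes of the cytotoxic list and of the inhibitory receptor list were both present. The cytotoxic protease gene granzyme B (Gzmb) was at 44.7 ± 1.32 CPM and perforin (Prf1) at 7.73 ± 0.483 CPM, a 5.76-fold difference in reads with a log2 ratio of 2.53 ± 0.13. Lamp1 (190 ± 4.24 CPM), Serpinb9 (83.0 ± 0.804 CPM) and Nkg7 (37.5 ± 2.90 CPM) were the other leading members, and 3 of the 12 genes were under 1 CPM. All 11 genes of the inhibitory receptor list, which are not all receptors, were above 1 CPM. The highest were Vsir (VISTA, listed as 4632428N05Rik, 158 ± 7.92 CPM), the ligand gene Cd274 (PD-L1, 153 ± 6.32 CPM), Btla (141 ± 3.61 CPM) and Lag3 (117 ± 5.05 CPM). The interferon response list had a median of 10.04 CPM, and its members included Stat2 (116 ± 1.37 CPM), Bst2 (55.7 ± 2.42 CPM) and Irf7 (24.4 ± 1.40 CPM).

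The median gene of the G1/S transition and DNA replication was far above that of G2/M, although the lists overlapped. The 16 G1/S genes had a median of 169 CPM and ranged from 1.304 CPM upwards, with Ccnd2 (cyclin D2) at 882 ± 50.7 CPM and the replication licensing genes Mcm5, Mcm2 and Mcm4 at 337 ± 12.4, 335 ± 1.82 and 315 ± 23.5 CPM. The 14 G2/M genes had a median of 4.29 CPM, led by Top2a (52.1 ± 5.64 CPM), Mki67 (27.1 ± 2.16 CPM), Cdc20 (13 ± 1.28 CPM) and Aurka (8.36 ± 0.748 CPM). The medians differed by 5.01 log2 units, or 32.2-fold on the CPM + 1 scale, in a permutation test with adjusted p = 0.00085. Ccnb1 (cyclin B1) had 41, 40 and 35 reads against 6166, 4410 and 5012 for Mcm5, a log2 ratio of -7.04 ± 0.24 (SD, n = 3).

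Each list was also placed in the whole transcriptome. Against 10000 random lists of the same size from all 44788 symbols, the medians of 18 of the 20 T cell state and pathway lists lay higher at an adjusted p under the threshold, and those of 0 of the 10 other-cell lists did (19 of all 30 lists passed at an unadjusted p under 0.05). The smallest adjusted p, 0.000667, is the smallest that the draws gave. The exceptions among the first were Th17 (adjusted p = 0.137) and G2/M (adjusted p = 0.0502), while Th2 passed narrowly (adjusted p = 0.05 after rounding). With values scaled for exon length the calls for CD4 lineage (adjusted p = 0.112), Th2 (adjusted p = 0.296), cytotoxic effector (adjusted p = 0.293) and interferon response (adjusted p = 0.135) were lost. Many listed symbols are silent, so the test was repeated among genes of at least 1 CPM. There 8 lists lay higher, namely T cell identity, activation, naive and quiescent, G1/S, glycolysis, NF-kB, IL-2 receptor and stress. G2/M (-2.40 log2 units, adjusted p = 0.0096) and B cell (-3.28, adjusted p = 0.0018) lay lower. These tests take genes as the unit, and genes are not replicates.

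**Figure D2:**
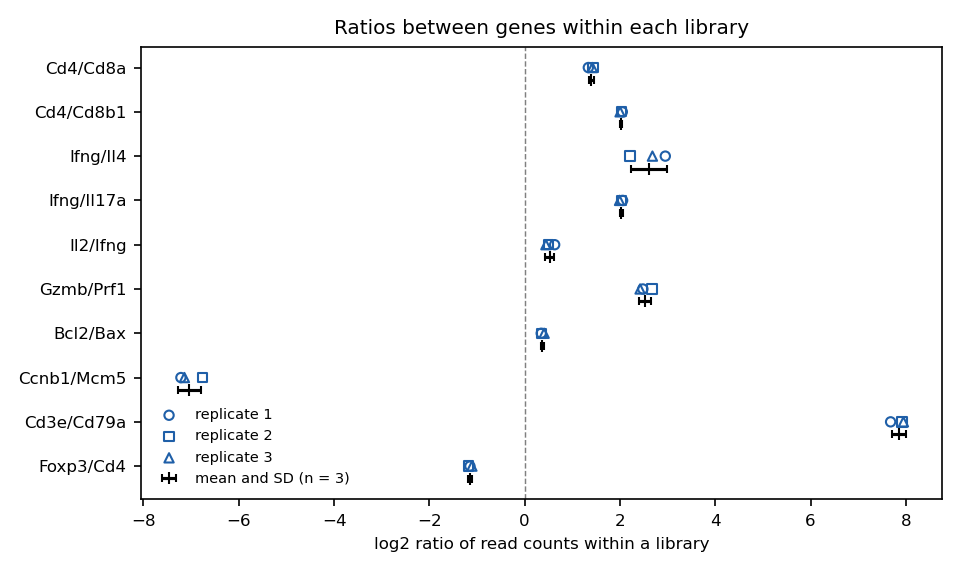
Log2 ratio of the read counts of paired genes within each library (x axis; rows name numerator and denominator), with one open symbol per replicate and the mean with its SD (n = 3) in black. The direction is the same in all 3 libraries for each ratio drawn, from -7.04 for Ccnb1 to Mcm5 to 7.85 for Cd3e to Cd79a.

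The replicates were close but differed by more than counting noise. Among 13500 genes of at least 1 CPM in at least 2 libraries, 1847 (13.7%) varied between the libraries in edgeR's likelihood-ratio test with the dispersion set to 0 (adjusted p under 0.05), a test that compares these libraries and not conditions. The median range between the libraries was 0.17 log2 units over all tested genes and 0.23 over the varying ones. The biological coefficient of variation was 0.049. Each pair of libraries differed, with 753 genes between replicates 1 and 2, 1227 between 1 and 3 and 1142 between 2 and 3, so none was a copy of another. Of the 10 genes with the widest range at a mean of at least 10 CPM, 9 were annotated pseudogenes. Rps2-ps13 stood at 989, 1390 and 445 CPM and Rps2-ps10 at 970, 489 and 1334 CPM in replicates 1, 2 and 3, with 94.5% and 97.2% of their 31-mers shared with other genes. The other pseudogenes were Gm7191, Rps13-ps4, Gm7803, Gm8292, Gm6580, Gm17082 and Gm8318, with ranges from 0.83 to 1.39 log2 units. The protein-coding exception was Mif (macrophage migration inhibitory factor), at 105, 97.6 and 219 CPM, with 39.1% of its 31-mers shared.

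Of the 247 tested genes of the fixed lists, 56 (22.7%) varied over all genes tested and 62 when adjusted over the list alone. The test calls abundant genes more readily, with 870 of the 2570 genes of at least 100 CPM varying, and the list genes were not compared with genes of like level. The median range over the 247 was 0.12 log2 units, and the widest among the 56 was 0.54 (Isg15, at 11.6, 7.97 and 10.5 CPM). Another 21 list genes, each at a mean of at most 3.91 CPM, had wider ranges of up to 1.45 and were not called. None of the 30 lists, markers of other cell types included, varied in its summed level more than random lists of like expression (smallest adjusted p = 0.947 in a one-sided random-list permutation test; 1 list at an unadjusted p under 0.05). Without replicate 3 the count of varying genes was 742, without replicate 1 it was 1120 and without replicate 2 it was 1193.

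**Figure D3:**
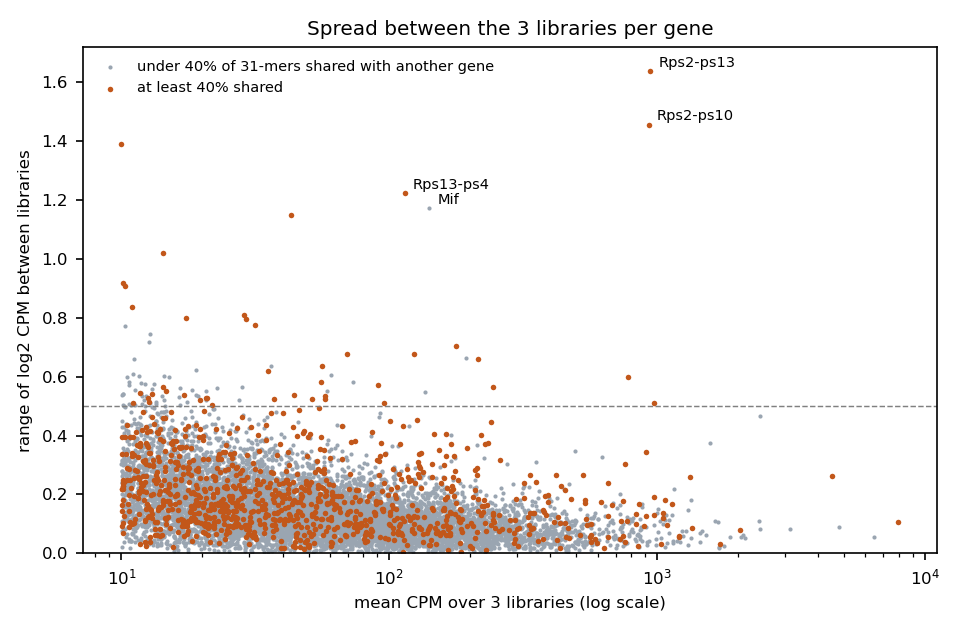
Range of log2 CPM between the 3 libraries (y axis) against mean CPM (x axis, log scale), one point per tested gene of at least 10 CPM, coloured orange where at least 40% of its 31-mers also occur in another gene's transcripts and grey where under 40% do. The dashed line marks a range of 0.5, and the labelled pseudogenes Rps2-ps13, Rps2-ps10 and Rps13-ps4 and the gene Mif lie well above it.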

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

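The restriction to genes with few shared 31-mers was chosen after seeing the data; the others were set beforehand. No paired analysis was possible because the libraries form a single group. Of 12 gene ratios, 11 kept their sign per kilobase of exon, and Bcl2 to Bax turned to -2.17; with 0.1 added to each count or a library left out all 12 kept their sign. No list variation between replicates crossed the threshold under any setting that gave a value. DESeq2 size factors, unscaled totals and both expression filters left the count of varying genes between 1668 and 1848. With fewer libraries it was 742 to 1193, against 1847. Among genes with under 5% shared 31-mers it was 1094, but fewer genes entered that test, so the lower count alone does not show less variation. The biological coefficient of variation among those genes was 0.0391. That coefficient ranged from 0.0436 to 0.0546 with a library left out, highest without replicate 1. Length scaling turned the activation minus naive difference to 0.84 and took the Th1 minus Th2 difference to 2.90, past the threshold; the cause was not tested.

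List levels, given in log2 units above the median random list, depended mostly on the background. Among genes of at least 1 CPM, a background of higher level by construction, the calls were lost for CD4 lineage (1.598), CD8 lineage (1.77), regulatory T cell (1.54), Th1 (0.58), Th2 (0.29), inhibitory receptor (1.37) and apoptosis (1.504). The sign turned there for Th17 (-2.33), cytokines (-1.25), cytotoxic effector (-0.22), G2/M (-2.40), interferon response (-1.27), B cell (-3.28), plasma cell (-0.64), NK cell (-1.24) and stroma and endothelium (-0.81). Another 6 lists had under 2 members left and gave no value, nor did the T cell identity minus monocyte and macrophage difference. With length scaling the calls were lost for CD4 lineage (5.51), Th2 (2.62), cytotoxic effector (2.44) and interferon response (3.12), and uncalled values turned for monocyte and macrophage (-0.34), dendritic cell (-0.39), erythroid (-0.24), mast cell and basophil (-0.54) and stroma and endothelium (-0.23). With means in place of medians the neutrophil list passed as lower (-1.39), and uncalled values turned for monocyte and macrophage (-1.13), dendritic cell (-0.81), NK cell (-0.12), erythroid (-1.18), mast cell and basophil (-0.74) and stroma and endothelium (-0.65). G2/M passed with a pseudocount of 0.1 (5.18). With a library left out, G2/M ranged from 2.30 to 2.49 and passed without replicate 2, Th2 ranged from 3.60 to 3.67 and failed without replicate 3 (adjusted p = 0.0527), and the uncalled mast cell and basophil value ranged from -0.041 to 0.076. The cause of these changes was not tested. Levels under 0.158 to 0.237 CPM could not be resolved at this depth.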

Other observations

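Tests in this part were chosen after the result was seen, except those of gene length and of nuclear RNA yield for the mitochondrial pattern. Antigen receptor genes, which were in none of the lists, gave a partial view of the receptor chains. The alpha constant gene Trac was at 411 ± 13.8 CPM and the beta constant genes Trbc1 and Trbc2 at 181 ± 7.25 and 374 ± 19.4 CPM (SD, n = 3). The delta constant gene Trdc was at 2.89 ± 0.616 CPM, and its reads were 0.883%, 0.542% and 0.679% of those of Trdc and Trac together in replicates 1, 2 and 3 (exact 95% intervals 0.685 to 1.12%, 0.364 to 0.778% and 0.490 to 0.917%). Symbols for whole loci, Tcra, Tcrb, Tcrd and Tcrg, held 752 ± 21.9, 891 ± 3.14, 7.01 ± 0.161 and 2.71 ± 0.273 CPM. Where in each locus their reads lie is not known, so the Trdc share covers the constant genes alone. Beta chain V segments had 3244, 2037 and 2480 reads, of which the Trbv13 family took 44.7 ± 1.71% and Trbv13-1 alone 24.9 ± 2.02%. Trbv5 and Trbv1 followed with 9.44 ± 0.916% and 9.09 ± 0.119%. Whether the 17016, 11309 and 13064 reads of Tcrb include V segment reads is not known. These shares therefore cover only reads listed under Trbv symbols.

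A hypothesis was that V segments removed in BALB/c mice by superantigens of endogenous mammary tumour viruses would be rare. The 5 segments Trbv12-1, Trbv12-2, Trbv15, Trbv16 and Trbv26 together held 5.65 ± 0.659% of Trbv reads, and their median share was 0.44% against 3.21% for 17 other segments. The difference did not pass an exact one-sided permutation test over the 26334 splits of the 22 segments (p = 0.0919). Trbv12-2 alone held 3.65 ± 0.449%. The test stays undecided, since other segments such as Trbv23 and Trbv24 were as rare and no other strain was compared.

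Reads divided among near-identical copies may account for part of the spread of the widest-ranging genes. With the 10 named genes that raised the question left out, 39.8% of the 83 other genes of at least 10 CPM that varied by over 0.5 log2 units had at least 40% of their 31-mers shared. Among the remaining genes of that level 10.9% did (odds ratio 5.37, 95% interval 3.44 to 8.38, Fisher's exact test p = 1.51e-11), and cuts at 20% and 60% gave odds ratios of 5.75 and 5.21. The sums over copies in the 46 of 48 ribosomal protein families without one of these 10 genes varied more, not less, than if the copies varied independently. Their median SD was 0.072 log2 units, against 0.063 with libraries permuted within each copy (middle 95% 0.055 to 0.068, one-sided permutation p for lower = 0.9996). Permuting also removes any shift between libraries that the copies share. Division among copies therefore cannot be told apart from other properties of such genes. In the families left out, Rps2 and Rps13, the sums had SDs of 0.056 and 0.041 against 0.84 and 0.67 for the most variable copy; a difference in library preparation stays open, and no biological explanation was tested.

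Mitochondrial mRNAs were higher in replicate 3 than in replicate 1, in 11 of 12 cases and by a median of 0.20 log2 units, while Rn18s-rs5, Lars2 and Malat1 were lower by -0.29, -0.47 and -0.38. Nuclear genes nearest in exon length and level moved by 0.058 (middle 95% of random sets 0.018 to 0.106), which leaves 0.14 log2 units. The mitochondrial median lay outside that range. However, how closely the nuclear genes matched was not measured, and shorter nuclear genes tended to be higher in replicate 3 (Spearman correlation with length -0.17). A length trend between the libraries therefore stays open as the cause. A lower yield of nuclear RNA cannot be told apart from no such change, because the median over 6 other nuclear RNAs was -0.056 with a bootstrap 95% interval from -0.45 to 0.079. Their log2 ratios were -0.46 for Kcnq1ot1, -0.43 for Jpx, -0.068 for Tug1, -0.044 for Neat1, 0.014 for Ftx and 0.14 for Pvt1. No biological explanation was tested.

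Ighm, the mu heavy chain constant gene (chromosome 12, 113418558 to 113422730, GRCm38), had 2406, 1816 and 2016 reads, or 136 ± 8.58 CPM, in cells nearly free of B cell markers. B cells left in the isolate are argued against as the main source by 7 abundant B cell transcripts, whose median level was 4.28% of Ighm. Among them were H2-Aa at 13.6 ± 0.0821 CPM, Igkc at 6.06 ± 0.606 CPM, Cd79a at 1.78 ± 0.102 CPM and Ighd at 1.03 ± 0.303 CPM. The median is the value of H2-Ab1. Whether H2-Aa and H2-Ab1 lost reads because BALB/c differs from the reference genome was not examined. Among the others, Igkc was at 4.47%, Cd79a at 1.31%, Cd79b at 1.30% and Ighd at 0.761% of Ighm. The bead selection for CD90.2 was meant to remove such cells, but how well it did so was not measured here. The highest of the 7 was Cd74 (18.7 ± 0.959 CPM, 13.8% of Ighm), and H2-Aa reached 10.02%. Reads shared with paralogs or pseudogenes are argued against by 0% of 31-mers shared with other GENCODE genes, a search that could not cover Igh, a symbol for the whole heavy chain locus without exons in the annotation, which held 165 ± 6.06 CPM. Unrearranged heavy chain transcripts made by the T cells remain a candidate explanation, untested because the counts do not show where in the gene the reads lie.

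Gapdh, singled out after its value was seen, was listed at 37.4 ± 0.839 CPM, far under Aldoa and Pkm of the same pathway, with 27.2% of its 31-mers shared.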
